A study of Mus musculus with 56 samples.

How the data were processed

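Total RNA from liver and kidney of male BALB/c mice, an inbred laboratory strain, was labelled with Cy3 and hybridised to one-colour NimbleGen expression arrays, per the labels. The files held 112 arrays of 56 samples, with 2 arrays per sample on different slides, and 12 slides that each held control and diet arrays. Each array carried 135054 gene probes for 42575 transcripts, with 3 probes for 35234 transcripts and 4 probes for 7336, and 2550 probes of random sequence. Every sample was placed in its group from the labels, which give tissue, diet, mouse number and, for diet mice, the time after the diet ended. The labels give control mice no time of their own apart from the letter of the set (A, B or C) that they share with diet mice, and controls of the same letter were used for each time. Replicates were separate mice, per the labels.

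The deposited array files give probe intensity on a linear scale. RMA was named as the software, per the submitters' processing notes, and its version, options and role were not given in the sources used here. In the deposited values, all arrays of a slide shared one distribution of intensity, and random-sequence probes reached far below the gene probes, as after a background correction. The deposited intensities had not been brought to one distribution across slides. The series matrix deposited by the authors gives log2 values, whose column medians lay between 7.77 and 8.35 in liver and between 8.96 and 9.25 in kidney. Set against the array files, 52 of its columns equalled the mean log2 intensity of the sample's own arrays within a tolerance of 0.001, so their scale is log2 with no centring, and 4 columns differed. All 4 belong to liver set C. The columns of control mouse 18 and diet mouse 18 held 1 array each. The columns of control mouse 20 and diet mouse 19 each held the first array of that mouse and the second array of the other. The assignment recorded with the array files was used. Under it Gpnmb was 5.84 and 6.20 on the arrays of control mouse 20 and 10.99 and 11.89 on those of diet mouse 19. With it the first arrays also correlated better with the second (0.112 and 0.117 within slides) than in exchange (0.041 and 0.004).

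Probe intensities were quantile normalized over all 112 arrays, summarised per transcript by median polish on the log2 scale, and averaged over the 2 arrays of a sample, so that a mouse counted once. No further background correction was applied, because the deposited values already appeared corrected, whereas the design fixed beforehand had foreseen normexp for uncorrected values. No transcript was filtered out. Gene names came from the identifiers of the array design matched to a table of mouse genes. This named 38643 transcripts with 21698 symbols, and 3932 transcripts stayed unnamed. Transcripts of near-identical families, such as immunoglobulin segments, Mup genes, Gsta1 with Gsta2 and Oas1a with Oas1g, can share probes, and their values are uncertain to that extent.

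Each tissue was fitted with limma (lmFit and eBayes) over its 6 groups, and diet was contrasted with control at each time. Interaction contrasts tested the change of the diet effect between times, and the difference between tissues was tested in a fit of all 12 groups with the mouse as a random block. This made 11 comparisons, of which 6 set diet against control and 5 tested a difference between effects. P-values were two-sided and adjusted by Benjamini-Hochberg over 42575 transcripts within each comparison, with a threshold of 0.05, and every adjusted p for a gene comes from limma. Standard errors are those of limma. Sets of genes were tested with camera in limma at a preset correlation of 0.01, adjusted over the 45 lists within a comparison, with camera at an estimated correlation and the directional fry test beside it. A list used 1 transcript per symbol, that with the highest mean in the tissue. A list is described by how many members passed over all transcripts and how many passed adjusted over the list alone.

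A transcript counted as not above background in a group when it lay at or under the 95th percentile of the random probes on every array of the group. A fold against such a group is given as a lower bound, the brighter group's mean over the dimmer group's mean of, per array, the higher of that percentile and the transcript's own value, and no fold is given where both groups were dim or the bound fell under 1. A log2 change or change of effect of such a transcript is a fitted value, used for the test, and its size is open. A transcript above the percentile on only 1 array counted as measured, so a fold can still rest on a mean under background. Median array intensity ranged from 235 to 384 in liver and from 521 to 706 in kidney. Between 27.8% and 70.9% of gene probes exceeded the random-probe percentile of their array. The percentile itself ranged from 75.7 to 1423 in liver and from 88.0 to 527 in kidney, so dim transcripts were bounded more loosely on some arrays than on others. The number of arrays limits the precision. Saturation was not given in the sources used here.

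The groups, the tests, the 45 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule the text names the 10 transcripts with the highest and the 10 with the lowest log2 change at 0 weeks, and 5 and 5 at 2 and 6 weeks, among those past the threshold in which every diet mouse lay on one side of the control mean. It also names up to 4 called members of a list described, transcripts called at all 3 times, and Mat1a, Bhmt, Gnmt, Pemt, Cbs and Dnmt1 in every comparison. Some genes that the rule selects are not reported here. Symbols that are only clone or model names were left out. Other genes are named only where the text says so.

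The alternatives were other normalizations and background corrections, the mean of probes in place of median polish, a filter on dim transcripts, the submitters' values, a trended and robust prior, only the groups compared, single arrays or slides, slide as a fixed term, sample weights, the replicate number as a block, other thresholds, other set tests and leaving out each mouse. A further 11 were added after the data were seen, for normexp with an offset of 50, single slides, liver set C arrays, kidney control arrays on slide 5 and 2 liver control mice of set B. Equal numbers in control and diet groups name different mice. Same-numbered control and diet mice deviated together in every pair only in liver set C (correlations across transcripts of 0.249 to 0.523 over 4 pairs) and kidney set B (0.151 to 0.262 over 4 pairs). There, under the rule that every pair exceed 0.1, the numbers were taken to pair the samples, from the data and not from the labels. The other tissue of the same sets fell short of the rule (kidney set C from 0.078 to 0.236, liver set B from -0.079 to 0.102). Most of the samples so paired also sat at neighbouring positions on their slides. Array position therefore cannot be told apart from a pairing of mice.

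The same fits were run on simulated transcript values of each sample with known changes. Noise was independent between transcripts, with the same spread in all sets of a tissue. Normalization, the summary of probes, slides and background were not simulated. The shares below therefore do not describe the noise of any 1 set. At a log2 change of 1, the simulated liver comparison recovered 61.2% of changed transcripts at 0 weeks, 49.3% at 2 weeks and 53.7% at 6 weeks, and the kidney comparison 85.1%, 71.6% and 73.1%. A log2 change of 2 was recovered for 98.5%, 86.4% and 90.9% in liver and 100%, 98.5% and 100% in kidney. At a log2 change of 0.5 the share was 10.4%, 4.48% and 7.46% in liver and 25.4%, 16.4% and 20.9% in kidney. The software was R 4.3.3 with limma 3.58.1, statmod 1.5.0, data.table (1.17.8) and matrixStats 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.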

Results

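Expression was measured in liver and kidney of 34 male mice, 22 of them with both tissues and 12 with 1. Diet mice had eaten for 8 weeks a diet low in methionine and without choline or folic acid, nutrients that supply methyl groups, and control mice had not. Tissue was taken when the diet ended (0 weeks, set A) or after 2 weeks (set B) or 6 weeks (set C) back on a normal diet. Liver samples numbered 6 control and 6 diet mice at 0 weeks, 4 and 4 at 2 weeks, and 4 and 5 at 6 weeks. Kidney samples numbered 6 and 5, 4 and 4, and 3 and 5. The study asks what this diet does to expression in male mice, and the sampling times ask what is left of the effect once the diet has ended. Hepatocyte and proximal tubule genes put all 56 samples in the tissue of their label. Levels are log2 intensity, and changes are log2 differences, diet minus control.

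The liver changed most at the end of the diet. Transcripts of activated macrophages led the rise. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 6.45 ± 0.43 to 13.08 ± 0.74 (SD, n = 6 each), a change of 6.63 (SE 0.29, adjusted p = 1.7e-14), and Mmp12, the macrophage elastase, rose by 6.42 (SE 0.31, adjusted p = 9.3e-14). Controls were not above background for either gene, so the rise was at least 35.7-fold for Gpnmb and at least 40.7-fold for Mmp12, whose other 2 transcripts did not pass. Moxd1, a monooxygenase related to dopamine beta-hydroxylase, fell from 12.75 ± 0.79 to 6.42 ± 0.93 (n = 6 each), 80.5-fold lower (change -6.33, SE 0.67, adjusted p = 7.2e-08). Its diet mean lay under the random-probe percentile of every diet mouse (7.15 to 8.69 on the log2 scale), so the size of this fold is uncertain.

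Ly6d, a surface protein of the Ly6 family, rose 40.3-fold (change 5.33, SE 0.35), and Cib3, a calcium-binding protein, 18.8-fold (4.23, SE 0.43). Against controls not above background, Timp1, an inhibitor of matrix metalloproteinases, rose at least 5.49-fold, the transcription factor Egr2 at least 4.33-fold. So did the transporter Abcc12 at least 3.36-fold, the vomeronasal receptor Vmn2r3 at least 2.95-fold, the cystine carrier Slc7a11 at least 2.34-fold, and Acod1, which makes itaconate in macrophages, at least 1.95-fold. Among falling transcripts, Pnpla3 and Pnpla5, lipases of the patatin family, changed by -3.48 (SE 0.39, 11.2-fold lower) and -3.81 (SE 0.46, 14.0-fold lower). The Pnpla5 mean of 6.36 in diet mice lay under the random-probe percentile of every diet mouse (lowest 7.15). The Cib3 mean of 7.44 in controls lay under that of every control mouse (lowest 7.45). Both folds are therefore uncertain. Rnase2a, a ribonuclease of the eosinophil family, fell at least 8.71-fold and Sorcs2, a sorting receptor, at least 2.44-fold, each to a level not above background. Ginm1 was 9.75-fold lower, the proteoglycan Cspg5 7.44-fold, the immunoglobulin light chain segment Igkv3-2 6.86-fold and Lrit2 6.11-fold, while the carrier Slc15a5 fell (adjusted p = 6.6e-06) to a level not above background, so no fold is given. Each bound is that of 1 transcript, and a second transcript measured in both groups changed by 4.72 for Timp1 and -3.21 for Rnase2a. All 6 diet mice lay on the same side of the control mean for each of these genes. A single mouse stood apart from its group for Vmn2r3, Sorcs2 and Lrit2 (control mouse 6), Pnpla5 (control mouse 5), Sorcs2 (diet mouse 2) and Igkv3-2 (diet mouse 6).

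**Figure D1:**
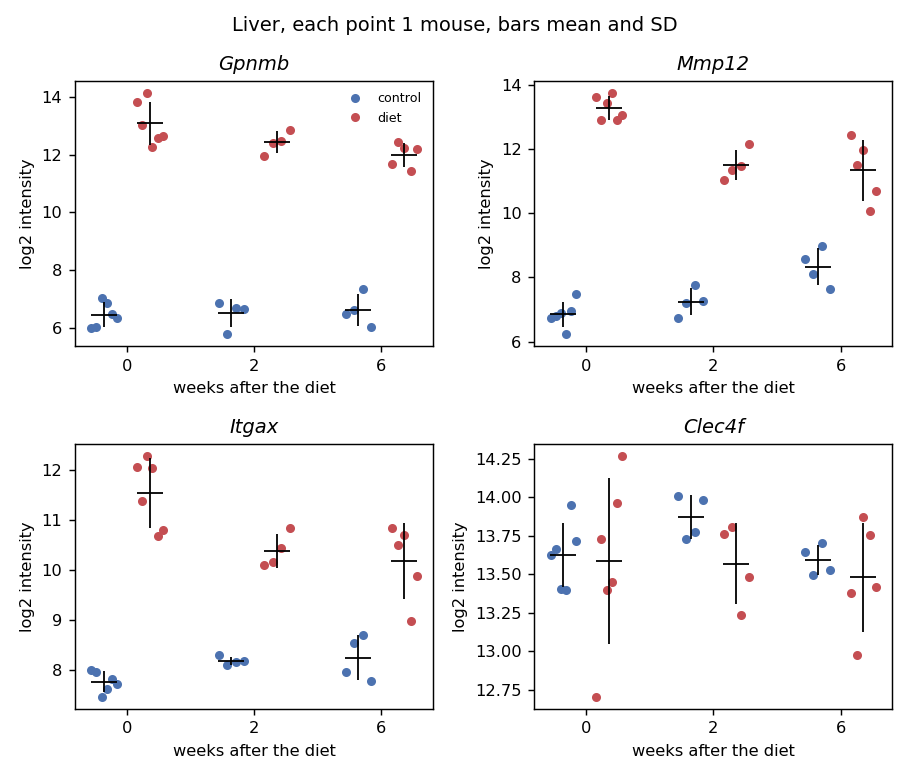
Log2 intensity of 4 macrophage genes in liver (vertical axes) by weeks after the diet (horizontal axes), with a point for each control mouse (blue) and diet mouse (red) and bars at the mean with SD. Gpnmb, Mmp12 and Itgax of the diet mice lay above all controls at each time, whereas Clec4f, a marker of resident Kupffer cells chosen after its values were seen, changed by -0.04, -0.30 and -0.11 and did not pass.

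Matrix, proliferation and inflammation lists rose together in the liver at 0 weeks. Of 24 genes of fibrosis and extracellular matrix, 22 rose and 2 did not pass (23 rose when adjusted over the list alone), with a median change of 1.55 (camera adjusted p = 4.3e-28). After Mmp12 came the collagenase Mmp13 (3.13) and the collagen cross-linking oxidase Lox, at least 1.35-fold above controls not above background. Cell cycle genes rose in 22 of 26 cases, 24 when adjusted over the list alone (median 1.85, adjusted p = 1.6e-24). Among them were Cdc20 (2.79), Cdk1 (2.50) and, from controls not above background, the mitotic cyclins Ccnb2 (at least 3.43-fold, and 2.52 for another transcript measured in both groups) and Ccnb1 (at least 4.41-fold). In the inflammation list, 17 of 22 rose, 18 adjusted over the list alone (median 1.35, adjusted p = 2.6e-22). They included the chemokines Ccl2 (3.57) and Ccl7 (at least 1.79-fold, from controls not above background), the receptor antagonist Il1rn (3.47) and the endotoxin co-receptor Cd14 (3.08). Interferon response genes rose in 20 of 29 cases, 21 adjusted over the list alone (median 1.03, adjusted p = 4.7e-19), with Cxcl10 (2.70), Cxcl9 (1.76) and Ifi44 (1.71). Within the 2 slides taken singly the medians were 1.5 to 1.53 for matrix, 1.84 to 1.91 for cell cycle, 1.36 to 1.39 for inflammation and 0.96 to 1.10 for interferon, and with slide as a fixed term they were 1.55, 1.85, 1.35 and 1.03.

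Markers of several non-parenchymal cell types also rose. Macrophage and Kupffer cell markers rose in 18 of 28 cases, 20 adjusted over the list alone (median 1.10, adjusted p = 9.9e-19, 1.02 to 1.15 within slides). Itgax (3.78, SE 0.28) and the beta-glucan receptor Clec7a (2.49) rose beside Gpnmb, as did Ms4a7, at least 4.48-fold above controls not above background. Stellate cell and fibroblast markers rose in 13 of 20, 17 adjusted over the list alone (median 0.72, adjusted p = 4.8e-13, 0.67 to 0.74 within slides). These included the collagens Col1a1 (2.49), Col3a1 (1.64) and Col1a2 (1.61), and vimentin, Vim (1.57). Of 14 neutrophil markers 6 rose, 10 adjusted over the list alone (median 0.95, camera adjusted p = 4.2e-05, and adjusted p = 0.19 with an estimated correlation). Lcn2 (3.03) and S100a8 (1.89) were among them. Cholangiocyte and progenitor markers rose in 8 of 18, again 8 with 2 lower adjusted over the list alone (median 0.49, adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation), with Krt23 (1.73), Prom1 (0.98) and Afp (0.94). Erythroid markers were lower in 5 of 13 cases, 5 also adjusted over the list alone (median -0.30, adjusted p = 0.049, and adjusted p = 0.32 with an estimated correlation), with Slc4a1 (-1.19) and the globin Hbb-b2 (-0.85). Endothelial markers did not pass as a list (1 of 19 higher and 2 lower, the same adjusted over the list alone, median -0.14, adjusted p = 0.37), with Lyve1 (1.64) higher and Flt1 (-0.54) lower. Hepatocyte markers did not pass either (2 of 24 lower, 2 adjusted over the list alone, median -0.06, adjusted p = 0.37).

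Lists of integrated stress, NRF2, p53 and injury genes also rose in the liver at 0 weeks. The integrated stress and amino acid response rose in 14 of 23 genes, 14 adjusted over the list alone (median 0.47, adjusted p = 7.4e-09, 0.40 to 0.53 within slides). It included Slc7a11, the transcription factor Atf3 (3.55), Nupr1 (2.87) and asparagine synthetase Asns (2.23). NRF2 and glutathione genes rose in 12 of 26, 14 adjusted over the list alone (median 0.34, adjusted p = 1.9e-08, 0.29 to 0.40 within slides). The glutathione transferases Gsta2 (3.16) and Gsta1 (3.08), Cbr3 (1.91) and the quinone reductase Nqo1 (1.69) rose most. Of 19 p53 response genes 11 rose, 12 adjusted over the list alone (median 0.46, adjusted p = 7.9e-08, 0.45 to 0.53 within slides). The cell cycle inhibitor Cdkn1a (2.98), Gdf15 (2.37) and Phlda3 (1.60) led this list. Injury genes known from kidney rose in 11 of 18, 12 with 1 lower adjusted over the list alone (median 0.99, adjusted p = 1.2e-08, 0.89 to 1.08 within slides), among them Lcn2 (3.03) and Cdkn1a. Acute phase genes rose in 6 of 25, 7 with 1 lower adjusted over the list alone (median 0.07, adjusted p = 0.020, and adjusted p = 0.47 with an estimated correlation). The metallothioneins Mt2 (2.58) and Mt1 (2.35) and the serum amyloid Saa3 (2.53) were among those that rose. The unfolded protein response did not pass (1 of 19 lower, 0 adjusted over the list alone, adjusted p = 0.51), and its called member was Ern1 (-0.56).

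Transcripts of lipid synthesis lay lower in diet mice than in controls in the liver at 0 weeks. Among 24 genes of fatty acid and triglyceride synthesis, 13 fell, 1 rose and 10 did not pass (15 fell when adjusted over the list alone), with a median of -0.51 (camera adjusted p = 2.1e-06, and adjusted p = 0.10 with an estimated correlation). Beside Pnpla5 and Pnpla3, the list's fall included Thrsp (-1.03) and acetyl-CoA carboxylase Acaca (-0.96), and within slides the median was -0.54 to -0.45. For Pnpla3 and Pnpla5 the controls of 0 weeks stood apart, at 12.21 and 10.16 against 8.33 and 6.52 in controls of 2 weeks. Diet mice of 0 weeks, at 8.73 and 6.36, lay near those later controls, which were measured on other slides. Lipid droplet and lipoprotein genes moved the other way in part, with 5 of 23 higher and 1 lower, the same counts adjusted over the list alone (median 0.05, adjusted p = 0.026, and adjusted p = 0.082 with an estimated correlation). Leading the rise were the droplet protein Cidec (4.01), Mogat1 (2.80) and lipoprotein lipase Lpl (1.75). Male-biased liver genes fell in 10 of 19 cases, 13 adjusted over the list alone (median -0.43, adjusted p = 2.0e-05, and adjusted p = 0.12 with an estimated correlation). Cyp2u1 (-1.46), the elongase Elovl3 (-1.14) and Hsd3b5 (-0.96) fell most. Female-biased liver genes were higher in 6 of 19 and lower in 1, 8 and 2 adjusted over the list alone (median 0.25, adjusted p = 0.018, and adjusted p = 0.19 with an estimated correlation), with Cyp39a1 (2.08) and Cyp2b9 (1.81). Fatty acid oxidation and PPAR targets did not pass as a list (6 of 28 higher and 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.058), although Cyp4a14 (2.54), Acot2 (2.03), Pdk4 (1.93) and the fatty acid transporter Cd36 (1.84) rose.

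The methionine and folate cycle, the pathway that the diet feeds, did not shift as a list in liver at 0 weeks (4 of 33 genes higher and 4 lower, the same adjusted over the list alone, median -0.07, adjusted p = 0.96). The mitochondrial folate enzymes Mthfd1l (2.42) and Mthfd2 (0.87) and Mat2a (0.59) were higher, and the glycine cleavage enzyme Amt (-0.80) was lower. Mat1a (0.10), Bhmt (-0.05), Gnmt (-0.14), Pemt (0.05), Cbs (-0.07) and Dnmt1 (0.19) did not pass. Choline and phospholipid genes were likewise mixed (3 of 22 higher and 4 lower, the same adjusted over the list alone, adjusted p = 0.58), with Pla2g4a (0.67) higher. DNA methylation genes were higher in 4 of 22, 5 adjusted over the list alone (median 0.10, adjusted p = 0.058), with Gadd45b (2.00) and Uhrf1 (1.43). Imprinted genes rose in 6 of 28, 7 adjusted over the list alone (median 0.16, adjusted p = 0.019, and adjusted p = 0.12 with an estimated correlation), with H19 (3.52) highest.

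By limma, 6938 of 42575 transcripts of 4655 named genes passed in liver at 0 weeks, 3986 higher and 2952 lower, and 22 of 45 lists passed. With an estimated correlation 10 lists passed, those of matrix, cell cycle, inflammation, interferon, macrophage, stellate cell, integrated stress, kidney injury, NRF2 and p53 genes. Taken singly, slide 1 called 8967 transcripts and slide 2 called 2016, with 99.9% and 100% of the calls keeping their sign, and with slide as a fixed term 7713 passed.

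**Figure D2:**
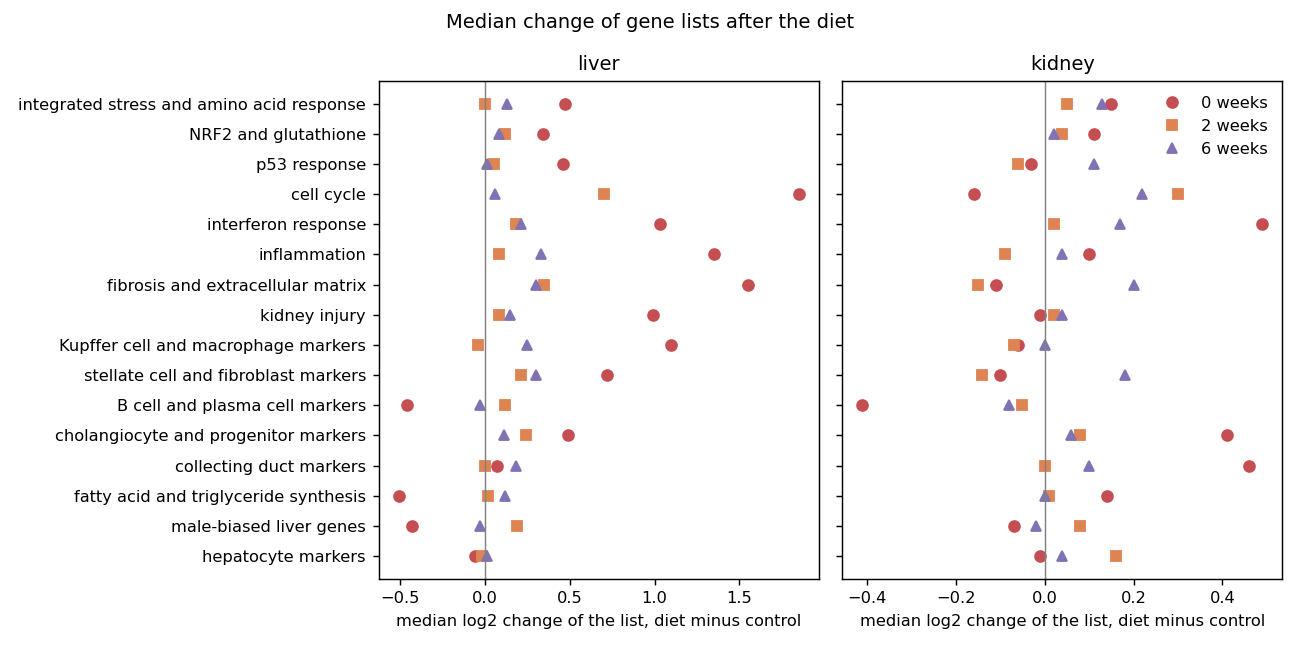
Median log2 change of gene lists (horizontal axes, diet minus control) in liver (left) and kidney (right), with a row for each list and a symbol for each time. The rows hold the 13 lists past the threshold at 0 weeks with an estimated correlation in either tissue and 3 others, and in liver cell cycle genes went from 1.85 at 0 weeks to 0.70 at 2 weeks and matrix genes from 1.55 to 0.35.

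At 2 weeks after the diet, 3 genes passed the threshold in liver, all higher. Gpnmb stood at 12.42 ± 0.38 against 6.50 ± 0.49 (SD, n = 4 each), at least 30.8-fold higher (change 5.92, SE 0.36, adjusted p = 4.7e-11), and a second Gpnmb transcript rose at least 1.73-fold. Mmp12 was 19.1-fold higher (4.25, SE 0.38, adjusted p = 2.4e-07). Itgax, the integrin CD11c of macrophages and dendritic cells, was 4.62-fold higher (2.21, SE 0.34, adjusted p = 0.0082). All 4 diet mice lay above the control mean for each gene.

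Of the lists at 2 weeks in liver, 13 passed with camera, 0 passed with an estimated correlation and 3 passed with fry, those of cell cycle, matrix and NRF2 genes. Cell cycle genes had 0 of 26 members past the threshold over all transcripts and 10 higher adjusted over the list alone (median 0.70, adjusted p = 2.1e-15, and adjusted p = 0.14 with an estimated correlation, 0.62 to 0.68 within slides). Matrix genes had 1 of 24 higher, Mmp12, and 6 adjusted over the list alone (median 0.35, adjusted p = 1.2e-09, and adjusted p = 0.23 with an estimated correlation, 0.39 to 0.43 within slides). NRF2 and glutathione genes had 0 of 26 past the threshold and 3 higher adjusted over the list alone (median 0.12, adjusted p = 0.0040, and adjusted p = 0.23 with an estimated correlation). Neutrophil markers lay below control (0 of 14 members past the threshold, 0 adjusted over the list alone, median -0.46, adjusted p = 0.00032, and adjusted p = 0.50 with an estimated correlation). Acute phase genes also lay below control (0 of 25, 0 adjusted over the list alone, median -0.12, adjusted p = 0.00032, and adjusted p = 0.50 with an estimated correlation). Macrophage markers did not pass as a list, with Gpnmb and Itgax higher of 28 and 5 higher and 1 lower adjusted over the list alone (median -0.04, adjusted p = 0.056). The mean of the neutrophil markers was 8.22 and 8.89 in control mice 11 and 15, 6.85 and 6.83 in the other 2 controls and 6.91 to 7.23 in the diet mice. The mean of the acute phase proteins was 14.39 and 14.61 in control mice 11 and 15, 13.38 and 13.16 in the other controls and 13.52 to 13.56 in the diet mice. Without these 2 control mice the median went from 0.08 to 0.39 for inflammation and from 0.18 to 0.31 for interferon genes. That of fatty acid synthesis genes went from 0.02 to -0.19. Medians were then 0.10 for neutrophil, 0.13 for acute phase, 0.18 for macrophage, 0.63 for cell cycle, 0.35 for matrix and 0.10 for NRF2 genes. Dropping controls high in neutrophil and acute phase genes raises such lists by construction, so no p-value is given. The 95th percentile of the random probes was 7.22 to 7.75 on the log2 scale in control mice and 7.04 to 7.21 in diet mice. Mat1a (0.05), Bhmt (-0.10), Gnmt (-0.07), Pemt (0.17), Cbs (0.04) and Dnmt1 (0.19) did not pass.

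In all, 4 transcripts passed in liver at 2 weeks, 4 higher and 0 lower by limma, against 2178 at an unadjusted p under 0.05. Leaving out control mouse 12, diet mouse 13 or diet mouse 14 left 2 calls each, and 5 passed without control mice 11 and 15. Slide 6 alone called 7 and slide 7 called 8, and with slide as a fixed term 57 passed, 49 of them higher.

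At 6 weeks in liver, Gpnmb, Mmp12, Trem2 and Itgax were above control. Gpnmb stood at 11.99 ± 0.42 in 5 diet mice against 6.62 ± 0.55 in 4 controls (SD), at least 10.6-fold higher (change 5.37, SE 0.34, adjusted p = 1.4e-10). Mmp12 was 7.95-fold higher (2.99, SE 0.36, adjusted p = 0.00013), the lipid receptor Trem2 3.84-fold (1.94, SE 0.34, adjusted p = 0.017) and Itgax 3.82-fold (1.93, SE 0.32, adjusted p = 0.011). The Trem2 mean of 7.08 in controls lay under the random-probe percentile of every control mouse (7.93 to 9.79), so its fold is uncertain. The interleukin 7 receptor Il7r rose (adjusted p = 0.017) from controls not above background, so no fold is given. Diet mouse 16 stood apart for it. Lower were the olfactory receptors Olfr1459 (adjusted p = 0.028) and Olfr1019 (adjusted p = 0.044), the potassium channel Kcnq5 (adjusted p = 0.035), Mpped2 and the cadherin Cdh18, all not above background in diet mice and the last 2 in neither group, so no fold is given for them. Diet mouse 20 stood apart for both olfactory receptors and control mouse 17 for Olfr1019. Mat1a (0.07), Bhmt (0.30), Gnmt (0.07), Pemt (0.02), Cbs (-0.04) and Dnmt1 (-0.04) did not pass.

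Interferon genes shifted upward at 6 weeks in liver, with Oas1a (1.25) the member past the threshold of 29 and 9 higher adjusted over the list alone (median 0.21, adjusted p = 1.3e-09, and adjusted p = 0.23 with an estimated correlation, 0.24 to 0.28 within slides). Matrix genes had Mmp12 past the threshold of 24 and 10 higher adjusted over the list alone (median 0.30, adjusted p = 6.3e-08, and adjusted p = 0.23 with an estimated correlation, 0.28 to 0.43 within slides). Of 28 macrophage markers 3 rose, Gpnmb, Itgax and Ms4a7 (at least 1.45-fold, from controls not above background, while another transcript measured in both groups, at 1.31, did not pass), while the Trem2 transcript used for the list (1.56) did not pass. In this list 7 were higher and 1 lower adjusted over the list alone (median 0.25, adjusted p = 1.7e-06, and adjusted p = 0.23 with an estimated correlation, 0.22 to 0.30 within slides). Stellate cell markers had 0 of 20 past the threshold and 5 higher adjusted over the list alone (median 0.30, adjusted p = 2.8e-06, and adjusted p = 0.23 with an estimated correlation, 0.29 to 0.30 within slides). Inflammation genes had 0 of 22 and 0 adjusted over the list alone (median 0.33, adjusted p = 0.0049, and adjusted p = 0.44 with an estimated correlation). With slide as a fixed term the medians were 0.21 for interferon, 0.30 for matrix, 0.25 for macrophage, 0.30 for stellate cell and 0.33 for inflammation genes. The count of lists past the threshold was 9 with camera, 0 with an estimated correlation and 0 with fry, and it was 13 with the replicate number as a block. Without control mouse 17, control mouse 20, diet mouse 16 or diet mouse 17 it was 5 each, and without diet mouse 19 it was 14.

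By limma, 31 transcripts of 24 named genes passed in liver at 6 weeks, 23 higher and 8 lower, and 86 passed with the replicate number as a block. With the mean of the probes 24 were higher and 4 lower, and after normexp with an offset of 50, 20 and 12. The count rose to 120 without control mouse 20, and to 101 and 61 without diet mice 19 and 20. It was 10 without control mouse 17, and 15, 11 and 4 without diet mice 16, 17 and 18. Slides 9 and 10 alone and a fit of only the groups compared called 1 each, and 135 passed with slide as a fixed term. From the submitters' values, where control mouse 20 and diet mouse 19 exchange second arrays, 1 passed.

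**Figure D3:**
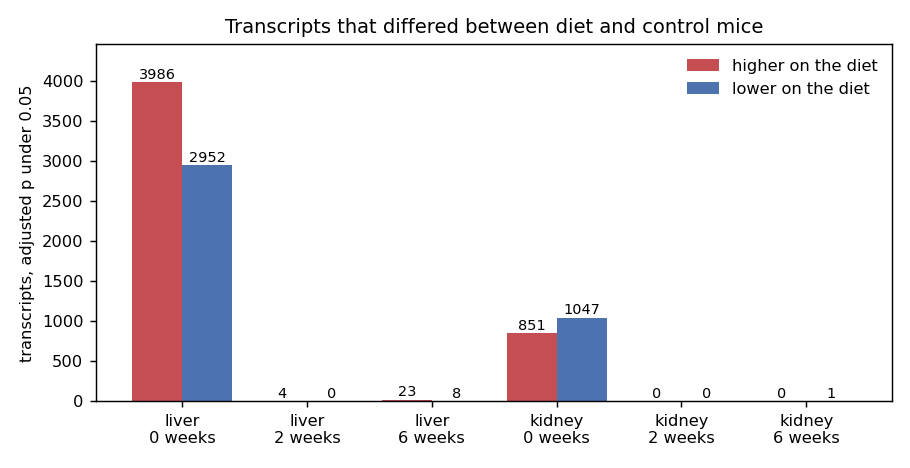
Number of transcripts past an adjusted p of 0.05 (vertical axis) higher (red) or lower (blue) in diet than in control mice, for each tissue and time (horizontal axis). The liver at 0 weeks had 3986 higher and 2952 lower, the kidney 851 and 1047, and the later times had between 0 and 31 in all.

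The kidney at the end of the diet showed lower immunoglobulin transcripts and Hsd11b1 and higher Bhmt and Cyp24a1. Jchain, the joining chain of secreted IgA and IgM, fell from 11.80 ± 0.71 (SD, n = 6) to 9.45 ± 0.51 (n = 5), 5.10-fold lower (change -2.35, SE 0.27, adjusted p = 4.2e-06). Bhmt, which remakes methionine from betaine, rose from 7.31 ± 0.52 to 8.96 ± 0.24, 3.15-fold (1.66, SE 0.24, adjusted p = 0.00010). Cyp24a1, which inactivates vitamin D, rose from 11.46 ± 0.84 to 13.53 ± 0.50, 4.18-fold (2.06, SE 0.41, adjusted p = 0.0036). Hsd11b1, which regenerates active glucocorticoid, fell from 11.89 ± 0.42 to 9.57 ± 0.26, 5.00-fold lower (-2.32, SE 0.27, adjusted p = 5.4e-06). Diet mouse 6 stood apart.

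Other kidney transcripts higher at 0 weeks were the amino acid carrier Slc7a12 (2.12, 4.35-fold) and the acyltransferase Mogat2 (1.84, 3.57-fold). So was Cyp2d12 (1.91, 3.76-fold, adjusted p = 3.8e-09). The elongase Elovl3 (2.87, SE 0.74, adjusted p = 0.024) and pentraxin Nptx1 (1.54) rose too. Their control means (6.54 ± 1.71 and 6.62) lay under every control mouse's random-probe percentile (lowest 6.76), so no fold is given. Elovl3 controls spread widely, with diet mouse 4 apart. In sets A, B and C, Slc7a12 was 7.30, 10.17 and 10.08 in controls and 9.43, 10.31 and 9.95 in diet mice. Cyp2d12 was 9.73, 11.91 and 12.94 against 11.64, 12.49 and 13.52. For both, controls were lowest at 0 weeks. The prolactin receptor Prlr rose in 4 transcripts measured in both groups, by 1.57 to 2.08, and at least 2.29-fold in another from controls not above background. From such controls 1 transcript of the kynureninase Kynu rose at least 2.05-fold, while one measured in both groups changed by 0.91 and did not pass, and the fatty acid receptor Ffar4 rose (adjusted p = 0.0013) with levels of both groups that overlap, so no fold is given. Light chain segments fell, Igkv6-23 8.17-fold (-3.03, SE 0.32, diet mouse 7 apart) and Igkv4-59 5.19-fold. Igkv6-17, Igkv3-2 and Igkv10-94 fell to means under every diet mouse's percentile (lowest 6.63), so no fold is given. Ctxn3, a membrane protein of kidney and brain, was 5.75-fold lower (-2.52), the ubiquitin ligase Rnf180 4.83-fold (-2.27) and Popdc3 at least 1.19-fold, and by -1.27 in a transcript measured in both groups. All 5 diet mice lay on the side of the change for these genes. Mat1a (not above background in controls), Gnmt (-0.33), Pemt (-0.42), Cbs (-0.06) and Dnmt1 (0.17) did not pass.

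**Figure D4:**
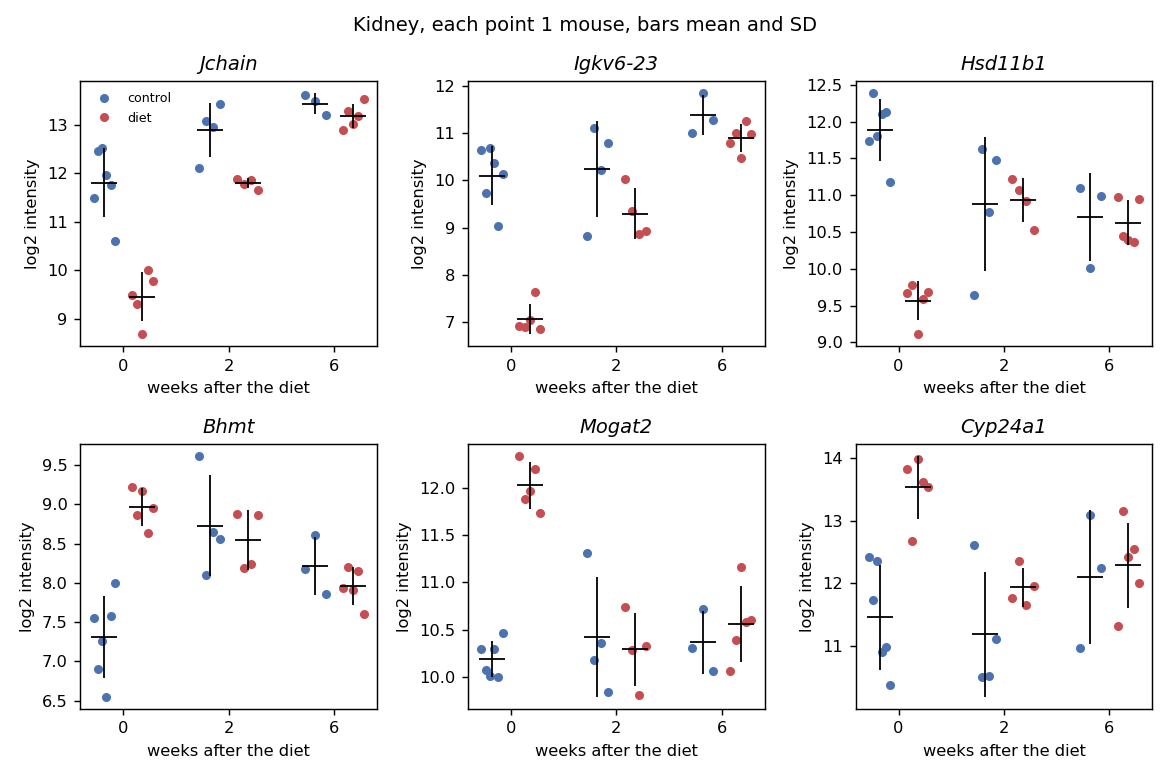
Log2 intensity of 6 genes in kidney (vertical axes) by weeks after the diet (horizontal axes), with a point for each control mouse (blue) and diet mouse (red) and bars at the mean with SD. Diet mice lay apart from controls at 0 weeks for Jchain, Igkv6-23, Hsd11b1, Bhmt, Mogat2 and Cyp24a1, and none of these passed at 2 or 6 weeks.

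Immune genes of the kidney moved in both directions at 0 weeks. B cell and plasma cell markers fell in 6 of 15, 9 adjusted over the list alone (median -0.41, adjusted p = 2.5e-07, -0.51 to -0.32 within slides, -0.37 with slide as a fixed term). Jchain and Cd22 (-0.78) were among them. T and NK cell markers fell in 3 of 19, 6 adjusted over the list alone (median -0.30, adjusted p = 8.2e-05, and adjusted p = 0.11 with an estimated correlation), with Gzma (-0.62) and with Cd3e, not above background in diet mice. Interferon response genes rose in 14 of 29, 19 adjusted over the list alone (median 0.49, adjusted p = 3.9e-12, and adjusted p = 0.11 with an estimated correlation, 0.50 to 0.59 within slides, 0.51 with slide as a fixed term). The factor Irf7 (1.24), Ifit1 (1.14), Mx2 (0.98) and Oas2 (0.93) led them. Erythroid markers fell in 3 of 13, 7 adjusted over the list alone (median -0.32, adjusted p = 0.0036, and adjusted p = 0.11 with an estimated correlation), with Hbb-b2 (-0.93) and Alas2 (-0.64). Cell cycle genes were lower in 4 of 26, 4 adjusted over the list alone (median -0.16, adjusted p = 0.0073, and adjusted p = 0.48 with an estimated correlation).

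Lists of ductal cells and of lipid genes rose in the kidney at 0 weeks. Collecting duct markers rose in 5 of 18, 12 adjusted over the list alone (median 0.46, adjusted p = 1.5e-09, 0.45 within each slide, 0.43 with slide as a fixed term). They included the water channel Aqp4 (1.24), the intercalated cell factor Foxi1 (0.66), the anion exchanger Slc26a4 (0.57) and the vasopressin receptor Avpr2 (0.57). The cholangiocyte list, whose genes also mark other ductal epithelia, had 8 of 18 higher and Cftr (-0.80) lower, 11 and 1 adjusted over the list alone (median 0.41, adjusted p = 2.2e-05, 0.40 to 0.47 within slides, 0.43 with slide as a fixed term). Muc1 (0.80) and Krt19 (0.61) rose most. Lipid droplet and lipoprotein genes rose in 3 of 23, 5 adjusted over the list alone (median 0.32, adjusted p = 0.0046, and adjusted p = 0.18 with an estimated correlation), with Apoa4 (1.08). Fatty acid synthesis genes rose in 3 of 24, 3 adjusted over the list alone (median 0.14, adjusted p = 0.014, and adjusted p = 0.36 with an estimated correlation), with Acacb (0.76). Adipocyte markers did not pass as a list (0 of 14, 0 adjusted over the list alone, median 0.32, adjusted p = 0.090). The mean of the adipocyte markers was 8.17 in control mouse 1, 10.03 to 11.62 in the other controls and 10.56 to 11.30 in the diet mice. Without control mouse 1 the medians were 0.17 for adipocyte, 0.28 for lipid droplet and 0.16 for fatty acid synthesis genes. Methionine and folate genes did not pass as a list (5 of 33 higher, 5 with 1 lower adjusted over the list alone, median 0.08, adjusted p = 0.058), although Bhmt, Ftcd (1.21), the glycine decarboxylase Gldc (0.58) and Shmt1 (0.47) rose. Androgen-dependent kidney genes fell in 3 of 12, 3 with 1 higher adjusted over the list alone (median -0.11, adjusted p = 0.042, and adjusted p = 0.33 with an estimated correlation), with Gusb (-0.70) and Acsm3 (-0.51). Kidney injury genes did not pass as a list (2 of 18 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.83), although the tubular injury marker Havcr1 (1.46) rose and Il18 (-1.07) fell.

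By limma, 1898 transcripts of 1470 named genes passed in kidney at 0 weeks, 851 higher and 1047 lower, and 15 of 45 lists, of which those of collecting duct, B cell and cholangiocyte genes passed with an estimated correlation. Control mice 6 and 7, with 1 array each on slide 5, stood apart on the first component of the spread within groups (57.9% of it). Of transcripts, 2926 passed without them, 1350 of these shared with the 1898, 1549 without their 2 slide 5 arrays, and 1206 without diet mouse 6. Slide 3 alone called 1210 and slide 4 called 279, 2747 passed with slide as a fixed term (54.5% higher, against 44.8%), and with median scaling 35.7% of 1702 calls were higher.

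In kidney at 2 weeks, Bhmt (-0.18, SE 0.28) and the other methyl cycle genes lay near control: Gnmt (0.17), Pemt (0.28), Cbs (-0.05) and Dnmt1 (0.12), with n = 4 in each group. Cell cycle genes shifted upward as a list, with 0 of 26 past the threshold, 0 adjusted over the list alone (median 0.30, adjusted p = 3.1e-10, and adjusted p = 0.44 with an estimated correlation, 0.31 to 0.34 within slides, 0.30 with slide as a fixed term). Hepatocyte markers also lay higher (0 of 24, 1 adjusted over the list alone, median 0.16, adjusted p = 0.0021, and adjusted p = 0.79 with an estimated correlation). Their mean was 11.07 in diet mouse 11, 10.13 to 10.22 in the other diet mice and 10.00 to 10.15 in the controls, and without diet mouse 11 the median was 0.01 (adjusted p = 0.51). Matrix genes lay lower (0 of 24, 0 adjusted over the list alone, median -0.15, adjusted p = 0.012, and adjusted p = 0.97 with an estimated correlation). No transcript passed with limma (count 0, with 1525 at an unadjusted p under 0.05), and 0 passed with slide as a fixed term, within slide 5 or slide 8, or with the replicate number as a block. Without diet mouse 11, 12 or 13 the count was 1 each, and of lists, 3 passed with camera, 0 with fry, 8 with camera without control mouse 11 and 5 without diet mouse 12.

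In kidney at 6 weeks, Spata31d1c, a testis gene, was lower (adjusted p = 0.00060) in 5 diet mice than in 3 controls but not above background in either, so no fold is given. Controls stood at 5.51, against 4.17 and 4.41 in the controls of 0 and 2 weeks. Bhmt (-0.26), Gnmt (-0.01), Pemt (0.12), Cbs (0.00) and Dnmt1 (-0.31) did not pass, and Mat1a was not above background at 2 or 6 weeks. Cell cycle genes shifted upward as a list (0 of 26 past the threshold, 1 adjusted over the list alone, median 0.22, adjusted p = 2.4e-05, and adjusted p = 0.51 with an estimated correlation, 0.17 to 0.28 within slides). Podocyte markers did so too (0 of 15, 0 adjusted over the list alone, median 0.15, adjusted p = 5.7e-05, and adjusted p = 0.51 with an estimated correlation, 0.19 to 0.25 within slides), and so did interferon genes (0 of 29, 1 adjusted over the list alone, median 0.17, adjusted p = 0.0032, and adjusted p = 0.91 with an estimated correlation, 0.14 to 0.23 within slides). With slide as a fixed term these medians were 0.22, 0.15 and 0.17. The background differed between these groups, with the 95th percentile of the random probes at 8.05 to 8.24 on the log2 scale in control mice and 7.20 to 7.83 in diet mice, and with 39.7% of transcripts not above it in controls against 31.5% in diet mice. The 1 call stood beside 2501 transcripts at an unadjusted p under 0.05. The count was 23 without control mouse 16, 71 without control mouse 17, 29 without control mouse 20, 5 without diet mouse 17 and 2 without diet mouse 18. It was 9 (1 higher) with median scaling, 14 (3 higher) after normexp with an offset of 50, 5 (2 higher) with slide as a fixed term and 0 within slide 11 or slide 12. Lists past the threshold numbered 7 with camera and 0 with fry, and 4 without control mouse 16, 4 without control mouse 20 and 3 without diet mouse 17.

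The difference between diet and control mice changed after the diet ended. In liver the effect on 1531 transcripts differed between 2 and 0 weeks, 455 higher and 1076 lower, and that on 1902 transcripts between 6 and 0 weeks, 669 higher and 1233 lower. Ly6d, which rose by 5.33 at 0 weeks, stood at 0.07 at 2 weeks and 0.72 at 6 weeks (changes of effect -5.26 and -4.61, adjusted p = 3.6e-06 and 7.8e-06). The effect on Mmp12 became smaller by 2 weeks (-2.16, SE 0.49, adjusted p = 0.0099) and by 6 weeks (-3.43, SE 0.47, adjusted p = 7.1e-05). That on Gpnmb changed by -0.71 (SE 0.46, adjusted p = 0.55) and -1.26 (SE 0.44, adjusted p = 0.11), which did not pass. The mean of the controls moved more between the sets than that of the diet mice for 190 of the 1531 (12.4%) and 378 of the 1902 (19.9%). At 0, 2 and 6 weeks Ly6d was 13.73, 8.25 and 8.30 in diet mice and 8.40, 8.18 and 7.58 in controls, so the diet mice moved. Pnpla3 was 8.73, 8.96 and 8.22 in diet mice and 12.21, 8.33 and 8.06 in controls, and Pnpla5 was 6.36, 6.64 and 6.01 against 10.16, 6.52 and 5.59, so the controls moved. Without control mouse 15 of set B the count at 2 weeks was 971, and without control mice 11 and 15 it was 378.

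In kidney 218 transcripts changed in diet effect between 2 and 0 weeks, 144 higher and 74 lower, and 165 between 6 and 0 weeks, 122 higher and 43 lower. The effect on Bhmt changed by -1.84 and -1.91, that on Hsd11b1 by 2.37 and 2.25, and that on Mogat2 by -1.97 and -1.64. The mean of the controls moved more than that of the diet mice for 100 of the 218 (45.9%) and 92 of the 165 (55.8%). At 0, 2 and 6 weeks Bhmt was 7.31, 8.73 and 8.22 in controls and 8.96, 8.55 and 7.96 in diet mice, and Hsd11b1 was 11.89, 10.88 and 10.70 against 9.57, 10.93 and 10.63, so both groups moved. Mogat2 was 10.19, 10.42 and 10.37 in controls and 12.03, 10.29 and 10.56 in diet mice, which moved. At 2 weeks the count was 107, 133 and 125 without diet mice 6, 7 and 8 of set A, 96 and 135 without control mice 13 and 14 of set B, and 108, 111 and 139 without diet mice 11, 12 and 14. At 6 weeks it was 107 without control mouse 2, 97 and 100 without diet mice 6 and 7, and 106 without diet mouse 20.

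Of the 6938 liver transcripts called at 0 weeks, Gpnmb, Mmp12 and Itgax transcripts made up the 4 called again in the same direction at 2 weeks, where independent lists would share 0.374 higher transcripts. At 6 weeks 20 were called again, 19 higher and 1 lower, where independent lists would share 2.15 and 0.555. Transcripts that had risen at 0 weeks had a median change of 0.92, and of 0.15 and 0.16 at the later times, with 72.4% and 72.5% still above control. Those that had fallen went from a median of -0.64 to -0.06 and -0.03, with 60.1% and 55.3% below control. The change of effect passed for 1492 of the 6938 by 2 weeks and 1770 by 6 weeks, whose direction follows largely from the choice of transcripts by their effect at 0 weeks. In kidney 0 of 1898 were called again by limma at 2 weeks or 6 weeks, and the change of effect passed for 202 and 148. Kidney transcripts that had risen (median 0.58) had medians of 0.00 and 0.08 at the later times, with 51.6% and 68.4% above control. Those that had fallen went from -0.57 to -0.01 at both, with 51.5% and 52.5% below control. The liver count at 2 weeks was 2 without control mouse 12, diet mouse 13 or diet mouse 14. At 6 weeks it was 8 and 45 without control mice 17 and 20, 9, 9, 4 and 73 without diet mice 16, 17, 18 and 19, and 31 without diet mouse 5 of set A, and in kidney 2 and 1 without control mice 17 and 20.

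Liver and kidney responded differently at 0 weeks. Mmp12 rose in liver and fell by 1.31 in kidney (adjusted p = 3.8e-18 for the difference), and Elovl3 moved the other way (-1.14 and 2.87). In both tissues Mogat2 was higher (1.53 and 1.84), Nptx1 was higher (1.96 and 1.54) and Igkv3-2 was lower (-2.78 and -2.44). The effect differed between tissues for 6039 transcripts, 3556 higher in liver and 2483 lower. Of 554 transcripts called in both tissues, 306 moved the same way, 161 higher and 145 lower, where independent lists would share 79.7 and 72.6, and 248 moved apart, 160 higher in liver and 88 higher in kidney, where independent lists would share 98 and 59. The tissues of a mouse correlated by -0.0065 on average in their deviations.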

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

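The tests of this part were chosen after the results had been seen, apart from the planned changes of effect and the planned comparison of liver with kidney. In 15 of 122 groups tested, a single mouse lay far from the others, and chance flags about 1 in 20 groups. The value is the gap to the nearest mouse as a share of the group's range. In liver controls at 0 weeks it was 0.642 for Vmn2r3, 0.685 for Sorcs2 and 0.830 for Lrit2, all in mouse 6, and 0.671 for Pnpla5 in mouse 5. In liver diet mice at 0 weeks it was 0.742 for Sorcs2 (mouse 2) and 0.701 for Igkv3-2 (mouse 6). At 6 weeks in liver it was 0.717 for Il7r (diet mouse 16), 0.828 for Olfr1459 (diet mouse 20), and 0.725 (diet mouse 20) and 0.911 (control mouse 17) for Olfr1019. In kidney diet mice at 0 weeks it was 0.834 for Elovl3 (mouse 4), 0.746 for Igkv6-23 (mouse 7) and 0.730 for Hsd11b1 (mouse 6). The level of the random probes stood apart in kidney control mouse 14 at 2 weeks (0.920) and kidney diet mouse 20 at 6 weeks (0.861).

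The diet effect differed between 2 and 0 weeks for 1531 liver transcripts and 218 kidney transcripts, and between 6 and 0 weeks for 1902 and 165. It differed between liver and kidney at 0 weeks for 6039. Among the genes named above, the liver effect had become lower by 2 weeks for Ly6d (-5.26), Vmn2r3 (-3.90), Abcc12 (-3.57), Acod1 (-3.05), Timp1 (-2.95), Slc7a11 (-2.78), Egr2 (-2.17), Mmp12 (-2.16) and Itgax (-1.57). It had become higher for Moxd1 (5.30), Rnase2a (4.46), Pnpla3 (4.10), Ginm1 (4.06), Pnpla5 (3.93), Sorcs2 (3.83), Slc15a5 (3.30), Cspg5 (3.10), Lrit2 (2.72) and Cdh18 (0.83). By 6 weeks it was lower for Ly6d (-4.61), Vmn2r3 (-4.34), Abcc12 (-3.91), Mmp12 (-3.43), Timp1 (-3.30), Slc7a11 (-3.28), Acod1 (-2.72), Egr2 (-2.51), Cib3 (-2.37), Olfr1019 (-2.01), Itgax (-1.84), Kcnq5 (-1.70) and Olfr1459 (-1.63). Higher by 6 weeks were the effects on Moxd1 (4.77), Pnpla5 (4.22), Sorcs2 (3.67), Pnpla3 (3.64), Ginm1 (2.87), Rnase2a (2.85), Lrit2 (2.56), Cspg5 (2.33) and Slc15a5 (1.92). Controls moved more than diet mice between the sets for Pnpla3 (12.21 at 0 weeks, 8.33 and 8.06 later) and Pnpla5 (10.16, then 6.52 and 5.59). They also did so for Ginm1 by 2 weeks and for Sorcs2, Olfr1459, Olfr1019 and Kcnq5 by 6 weeks.

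In kidney the effect had become lower by 2 weeks for Kynu (-2.72), Mogat2 (-1.97), Bhmt (-1.84) and Cyp2d12 (-1.32), and higher for Rnf180 (2.70), Ctxn3 (2.66), Igkv6-17 (2.41) and Hsd11b1 (2.37). By 6 weeks it was lower for Kynu (-2.06), Bhmt (-1.91), Mogat2 (-1.64), Cyp2d12 (-1.33) and Spata31d1c (-1.28). It was higher by 6 weeks for Igkv6-23 (2.55), Ctxn3 (2.31), Hsd11b1 (2.25), Igkv4-59 (2.12) and Jchain (2.09). Controls moved more than diet mice at both times for Kynu, Ctxn3 and Cyp2d12, by 2 weeks for Bhmt, and by 6 weeks for Hsd11b1 and Spata31d1c.

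Each count was set against other ways of splitting the same mice into 2 groups, which asks whether a grouping by chance gives as many. Each share was judged at 0.05, with no adjustment over the counts tested. In liver at 0 weeks, 1 of 100 splits reached the 6938 calls, the real one, and the highest other, which exchanged 1 control and 1 diet mouse, gave 2657, so chance can be excluded. For its 22 lists 2 of 100 did, so chance can be excluded by share, although the highest other split also gave 22. The other splits had a median of 12 lists, so camera at the preset correlation calls many lists in an arbitrary split too, with a median of 8 in liver at 2 weeks and 5 in kidney at 0 weeks. In liver at 2 weeks, 2 of 35 splits reached the 4 calls (highest other 4) and 4 of 35 the 13 lists (highest other 13). Chance cannot be excluded for either. For the 4 called again, 1 of 35 did (highest other 1), the lowest share possible, which alone does not settle it. In liver at 6 weeks, where the numbers were taken as pairs from these same data, splits that ignore the pairs reached the 31 calls in 16 of 100, the 9 lists in 7 of 100 (highest other 13) and the 20 transcripts called again in 5 of 100 (highest other 88). The highest of these splits gave 1905 calls with 6 in common with the real ones. It set control mice 16, 17 and 20 and diet mice 19 and 20 against control mouse 18 and diet mice 16, 17 and 18. Only 8 splits part all 4 pairs, the others exchanging control and diet within some pairs, which is too few for a share under 0.05. With the replicate number as a block, the real split gave 86 calls (highest other 2, 1 of 8 at the real count) and 13 lists (highest other 8, 1 of 8).

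In kidney at 0 weeks, 2 of 100 splits reached the 1898 calls, so a grouping by chance can be excluded by share, although the highest other split also gave 1898, with 38 in common with the real calls. That split put control mice 6 and 7, which have an array on slide 5, on the same side. Within slides 3 and 4 the real comparison gave 1210 and 279 calls, and with slide as a fixed term 2747. For the 15 lists 1 of 100 did, so chance can be excluded by share, although narrowly (highest other 14). In kidney at 2 weeks, every split reaches a count of 0, 35 of 35 for the calls by limma (highest other 0) and 35 of 35 for those called again (highest other 0), so the splits say nothing there. For the 3 lists 25 of 35 did (highest other 13). The numbers were taken as pairs here too, and of the 8 splits that part all 4 pairs, too few for a share under 0.05, 8 of 8 reached the 0 calls (highest other 0) and 6 of 8 the 3 lists (highest other 13). In kidney at 6 weeks, 35 of 56 splits reached the 1 call (highest other 38), so chance cannot be excluded for it. The 0 called again are reached by 56 of 56 (highest other 2), which says nothing. For the 7 lists 1 of 56 did, but narrowly (highest other 6), and 0 lists passed with fry. Leaving out single mice gave 3 to 10 lists, so the share alone does not settle it. The background level, higher in every control mouse (8.05 to 8.24) than in the diet mice (7.20 to 7.83), also cannot be set apart from the groups there. For each change of effect, 1 of 50 splits, the real one, reached the count. The highest others were 0 and 642 in liver at 2 and 6 weeks, 1 and 20 in kidney, and 218 for liver against kidney, also with 1 of 50 at the real count. With the later mice split only so that every pair is parted, and the mice of 0 weeks split otherwise, 1 of 50 reached the count in liver at 6 weeks (highest other 1) and in kidney at 2 weeks (highest other 2). For all 5, every other split regrouped the mice of 0 weeks and so removed the effect at that time. The counts thus show an effect at 0 weeks beyond a grouping by chance. They cannot tell whether it changed with time or differed between tissues.

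The 100 liver transcripts that rose most at 0 weeks (median change 3.36, SE 0.17) still lay above control at 2 weeks (0.88, SE 0.16, 90 of 100 above control) and 6 weeks (0.72, SE 0.21, 88 of 100). The arrays of 1 slide could give this, but the lowest median over the 4 slides was 0.66 (SE 0.22), which argued against it. It argued against 1 diet mouse as the source that the lowest median with 1 diet mouse left out was 0.62 (SE 0.21). More macrophages of every kind would raise the resident cell markers Clec4f, Timd4, Vsig4 and Cd5l at least as much. These markers were chosen after the data were seen. Their medians at 2 and 6 weeks were -0.28 (SE 0.17) and -0.06 (SE 0.22), so they did not rise. The difference from the 100 was -1.16 (SE 0.23) and -0.79 (SE 0.30), which argued against more macrophages of every kind as the whole source. The 100 were chosen by the size of their rise and not as macrophage genes, so this difference says little about macrophage number. Against the other 24 members of the macrophage list, the differences of -0.38 (SE 0.23) and -0.37 (SE 0.25) decide nothing. Recruited or altered macrophages that stay in the liver are a hypothesis that remains open, as no cell counts or sorted cells were measured.

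Of 151 immunoglobulin transcripts in kidney at 0 weeks, 58 were lower and 1 higher, and the median was -0.66 (SE 0.12) over all 151 and -1.40 (SE 0.18) over the 58, which were chosen by their fall. Less blood in the tissue might lower them, but erythroid markers changed by a median of -0.32 (SE 0.08), above that of all 151 by 0.34 (SE 0.15), which argued narrowly against blood as the whole source and left a part open. Without the 2 control mice with an array on slide 5 the median was -1.73 over the 58 and -0.83 over all, and within slides 3 and 4 it was -0.84 and -0.60 over all, which argued against the slide. Over all 151 the median was -0.63 (SE 0.12), -0.29 (SE 0.13) and -0.49 (SE 0.28) in liver at 0, 2 and 6 weeks, and -0.41 (SE 0.07) and -0.14 (SE 0.13) in kidney at 2 and 6 weeks. A loss of plasma cells or of their output on the diet is a hypothesis that remains open.

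Liver at 6 weeks gave fewer calls from the submitters' values (1) than from the array files (31). With 2 arrays exchanged between the groups as in the submitters' values the count was 2, as an exchange would give. With the 2 arrays left out that are absent from those values it was 24, which argued against their absence as the source. The arrays might instead be exchanged in the files and not in the submitters' values, but each first array correlated better with its own second array, by at least 0.071, which argued against it. No biological explanation was tested for this pattern.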

How the results depend on the processing

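Over the named genes, 5387 of 6145 values under other settings kept direction and side of the threshold, 758 kept direction only, and 0 reversed. With single mice left out, 3059 of 3411 stayed and 352 kept direction only. The majority direction of the calls in kidney at 0 weeks reversed, from 44.8% higher to 54.5% with slide as a fixed term and 55.0% without the 2 control mice with an array on slide 5. Of lists past the threshold, the median went from 0.08 to -0.03 for NRF2 genes in liver at 6 weeks and from -0.08 to 0.05 for ribosomal proteins in kidney at 0 weeks on 1 slide. Without liver control mice 11 and 15, medians at 2 weeks went from -0.46 to 0.10 for neutrophil, -0.12 to 0.13 for acute phase, 0.19 to -0.07 for male-biased and -0.27 to 0.07 for female-biased genes, and the change of effect was 378. The cause of a change was not tested unless stated. The signal over background limits dim genes, since on the array with the highest random-probe level 27.8% of gene probes exceeded it. Nothing moved by over 1.5 times with quantile normalization within each tissue, with a trended or robust prior, or without the mouse as a block.

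Thresholds and set tests, fewer calls by construction: with adjusted p under 0.01, 4153 passed in liver at 0 weeks, 7 in liver at 6 weeks and 701 in kidney at 0 weeks, and with at least a 1.5-fold change 915 in kidney at 0 weeks. Camera with an estimated correlation called 10, 0 and 0 lists in liver and 3, 0 and 0 in kidney. Fry called 3 and 0 in liver and 0 and 0 in kidney at 2 and 6 weeks, and camera with all transcripts of a gene called 11 lists in kidney at 2 weeks.

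With the first array of each sample only, calls were 4227, 14 and 112 in liver and 3420, 4 and 3 in kidney, and changes of effect 858 and 1124 in liver and 510 and 324 in kidney. First arrays gave lists 4 and 5 in liver at 2 and 6 weeks and 3 in kidney at 6 weeks, and liver transcripts called again 10 and 39. With the second array of each sample only, calls were 3976, 2 and 5 in liver and 301, 1 and 16 in kidney, and changes of effect 484 and 523 in liver and 2 and 38 in kidney. For second arrays the tissue difference was 2620, lists 0 in kidney at 6 weeks, and liver transcripts called again 2 and 5. With the arrays of slide 2 only, 2016 passed in liver at 0 weeks. In kidney at 0 weeks slide 3 only gave 1210 and slide 4 only 279. In liver, slide 6 only gave 7 and slide 7 only 8 at 2 weeks, and slide 9 only gave 1 and slide 10 only 1 at 6 weeks. In kidney at 6 weeks slide 11 only gave 0 and slide 12 only 0 by limma.

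With median scaling of each array, calls in kidney were 1 at 2 weeks and 9 at 6 weeks, lists at 6 weeks were 5 in liver and 4 in kidney, and 1 kidney transcript was called again at 6 weeks. With the mean of the log2 probe values, 48 passed in kidney at 6 weeks, 252 in its change of effect at 6 weeks, and 6 lists in kidney at 2 weeks. Normexp with offset 0 gave 0 calls in kidney and 5 lists in liver at 6 weeks. Normexp with offset 50 gave 1 and 14 calls in kidney at 2 and 6 weeks, with 1 called again at 6 weeks. With only transcripts above the median level, calls at 6 weeks were 11 in liver and 0 in kidney, lists 5 and 2, and liver transcripts called again 11, from fewer transcripts tested. With the submitters' processed values, calls were 2 and 1 in liver at 2 and 6 weeks and 13 in kidney at 6 weeks, lists 6 in kidney at 2 weeks, and liver transcripts called again 2 and 1.

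With only the groups compared in the fit, calls were 12 and 1 in liver at 2 and 6 weeks, 894 and 0 in kidney at 0 and 6 weeks and 139 in the kidney change of effect at 2 weeks. This fit gave lists 14 in liver at 6 weeks, and liver transcripts called again 9 and 1. With sample weights, calls were 103 and 3 in liver at 2 and 6 weeks and 3048 and 1 in kidney at 0 and 2 weeks. Sample weights gave changes of effect at 2 weeks 3193 in liver and 636 in kidney, lists 8 in kidney at 2 weeks, and liver transcripts called again 73 and 2. With slide as a fixed term, calls were 57 and 135 in liver at 2 and 6 weeks and 5 in kidney at 6 weeks, changes of effect 2365 in liver at 2 weeks and 609 and 462 in kidney, and liver transcripts called again 47 and 94.

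With the replicate number as a block (replicate block), calls were 2 and 86 in liver at 2 and 6 weeks and 293 and 0 in kidney at 0 and 6 weeks, and lists 8 in liver at 2 weeks and 9 in kidney at 0 weeks. Liver at 0 weeks gave 5101. Over 21 same-numbered pairs the correlation ran from -0.273 to 0.523 with a median of 0.155, 13 exceeded 0.1, and in 10 the best match was the same number. Outside liver at 6 weeks and kidney at 2 weeks the numbers were not taken as pairs. In those 2 comparisons the block changed no call or count by over 1.5 times apart from the 86 liver calls and single named genes.

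In liver at 6 weeks, 2 second arrays exchanged as in the submitters' values gave 2 calls with 2 called again, and 2 arrays left out and 2 exchanged gave 2 calls with 2 called again. Without the 2 arrays absent from the submitters' values 5 lists passed, and without mice 18 of both groups, control mouse 20 and diet mouse 19 the change of effect at 6 weeks was 889. Without the 2 kidney control mice with an array on slide 5, 2926 passed at 0 weeks and 426 and 502 in the changes of effect.

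With each mouse left out in turn, calls ranged from 5864 to 6741, 2 to 6 and 4 to 120 in liver and from 1206 to 2155, 0 to 1 and 1 to 71 in kidney. Changes of effect ranged from 971 to 1904 and 1447 to 2125 in liver and from 96 to 269 and 97 to 233 in kidney, and the tissue difference from 5119 to 6178. Lists ranged from 21 to 25, 12 to 16 and 5 to 14 in liver and from 12 to 17, 2 to 8 and 3 to 10 in kidney. Transcripts called again ranged from 2 to 6 and 4 to 73 in liver and from 0 to 0 and 0 to 2 in kidney.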

Other observations

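The tests of this part beyond the planned lists were chosen after the results had been seen. Several gene groups not described so far passed in liver at 0 weeks. Adipocyte markers rose in 4 of 14 cases, 4 adjusted over the list alone (median 0.10, adjusted p = 0.018, and adjusted p = 0.17 with an estimated correlation). The droplet protein Cidec (4.01), the nuclear receptor Pparg (2.11) and Lpl (1.75) were among them. Podocyte markers, which other liver cells share in part, rose in 6 of 15, 7 with 1 lower adjusted over the list alone (median 0.46, adjusted p = 0.020, and adjusted p = 0.22 with an estimated correlation), with Synpo (1.74) and Wt1 (1.10). Clock genes were lower in 2 of 20, 2 adjusted over the list alone (median -0.31, adjusted p = 0.026, and adjusted p = 0.19 with an estimated correlation), namely Hlf (-0.84) and Cry1 (-0.55). B cell markers did not pass as a list (2 of 15 higher and 4 lower, 2 and 6 adjusted over the list alone, adjusted p = 0.090), with Jchain (-1.36) lower. Bile acid genes did not pass either (3 of 19 higher and 6 lower, 3 and 8 adjusted over the list alone, adjusted p = 0.11), although the exporters Abcc3 (1.10) and Abcc4 (0.99) rose. Xenobiotic genes were mixed (3 of 25 higher and 5 lower, 4 and 5 adjusted over the list alone, adjusted p = 0.98), with Cyp1b1 (at least 1.41-fold, from controls not above background) higher and Cyp2c29 (-1.70) lower.

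Further genes above control in liver at 6 weeks, chosen after their values were seen, were the chemokine receptor Cxcr4 (1.56, SE 0.25, 2.96-fold, adjusted p = 0.0095) and the antiviral synthetase Oas1g (1.48). Timp1, Scube1 (at least 1.08-fold) and Tuba8, whose groups overlap, were higher from controls not above background, so no size is given for Timp1 and Tuba8. Also above control were Mmp23 (1.28), Spats2l (1.23), Endod1 (1.20) and the oxidase Acox3 (1.09). In kidney at 0 weeks, podocyte markers rose in 3 of 15, 6 adjusted over the list alone (median 0.26, adjusted p = 0.0083, and adjusted p = 0.34 with an estimated correlation), with Wt1 (0.52) and Ptpro (0.49). Loop of Henle markers rose in 1 of 17, 2 adjusted over the list alone (median 0.21, adjusted p = 0.00067, and adjusted p = 0.23 with an estimated correlation), the calcium binder Calb1 (0.41). Outside the lists that passed in kidney, the betaine carrier Slc6a12 (1.07) rose and Cyp2b10 (-1.95) fell.

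Resident Kupffer cell markers did not pass in liver at any time. At 6 weeks Clec4f changed by -0.11 (SE 0.22), Timd4 by -0.48 (SE 0.30), Vsig4 by -0.01 (SE 0.24) and Cd5l by 0.74 (SE 0.39). With the arrays of control mouse 20 and diet mouse 19 exchanged, Gpnmb at 6 weeks changed by 4.10 (adjusted p = 0.0019), and from the submitters' values by 4.50 (adjusted p = 0.00080), against 5.37 from the array files. Other genes kept their direction with the arrays exchanged but not the threshold: Mmp12 (2.30, adjusted p = 0.099), Trem2 (1.77, adjusted p = 0.099), Cxcr4 (1.44, adjusted p = 0.089), Oas1a (0.95, adjusted p = 0.22), Itgax (1.49, adjusted p = 0.30) and Spats2l (0.83, adjusted p = 0.42). So they did from the submitters' values: Mmp12 (2.37, adjusted p = 0.13), Trem2 (1.96, adjusted p = 0.11), Cxcr4 (1.34, adjusted p = 0.18), Oas1a (1.15, adjusted p = 0.12), Itgax (1.40, adjusted p = 0.47) and Spats2l (0.86, adjusted p = 0.49). From the array files these genes changed by 2.99, 1.94, 1.56, 1.25, 1.93 and 1.23. The first array of control mouse 20 gave a Gpnmb level of 5.84 and the second 6.20, and those of diet mouse 19 gave 10.99 and 11.89.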
